A study of Rattus norvegicus with 7 samples.

How the data were processed

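Messenger RNA of colon crypts was analysed from 2 libraries, 1 of the proximal and 1 of the distal colon, each pooled from 7 rats per the labels. The groups followed the sample titles, and the columns of the deposited table were assigned through their printed sample names. The 5 libraries of chromatin immunoprecipitation were not analysed here.

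Per the submitters' processing notes, the names CASAVA and TopHat2 and the genome build rn4 go with the RNA samples, with no versions given. The table holds, per the file headers, 1 row per gene with its locus, a value for each region, a log2 fold change, a test statistic, a p-value, a q-value and a call. No source used here names the program that made the table. The values were taken as FPKM of the authors, fragments scaled by transcript length and library size, because they are not whole, differ in sum between the libraries (413025 and 463560) and rise at low levels in steps that depend on the gene. How the authors scaled the libraries against each other is not given in the sources used here. The p-value of the deposited table equals the two-sided normal tail of its test statistic to within 2.76e-06, so the ratio of the deposited log2 fold change to that statistic was used as the standard error it implies. With 1 library per group this error comes from the model behind the deposited table, and it does not measure variation between rats. Where 1 value is 0, the deposited log2 fold change holds a placeholder and was not used.

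Of 16492 rows, 10100 were marked as tested, 6369 as not tested, 22 as too low in data and 1 as failed. The 23 rows of the last 2 kinds and 1 row given again for the same gene were left out, which kept 16468 genes. Loci start at 0 in the table: of 1188 olfactory receptor loci under 1100 bases, 1187 have a length that is a multiple of 3 when 1 is added to the start, and positions here are given that way. Of the 16468 symbols, 13309 were current symbols in the RefSeq gene table of the GRCr8 assembly, which was used for older names only. In the table, 1312 genes share their locus with another gene, and their values can hold reads of the neighbour. Genes with many near-identical copies in the genome were often near 0, such as Rpl36 at 0 and 0 FPKM and Hmgb1 at 0.886 and 0.693 FPKM in the proximal and distal library, so a value of 0 is given as listed and not as absence.

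Total read numbers are not given in the sources used here. Among genes at 0 in the other library, the commonest p-value of the deposited table, taken to mark a single read, was 0.149 for 232 proximal rows and 0.169 for 234 distal rows. For olfactory receptor genes with that value, of about 942 bases, it corresponded to 0.142 FPKM in the proximal library (8 genes) and 0.113 FPKM in the distal library (4 genes), so that 3 reads stand near 0.426 and 0.339 FPKM for genes of this length, and lower for longer genes. Across 1494 low rows above 0 in both libraries the commonest ratio of distal to proximal FPKM was 0.859, as for 1 read in each, which would put the distal library at 1.16 times the depth of the proximal one. The single-read values of the few olfactory receptor genes give 1.25, so the ratio is known only roughly. No fold is given where the lower value is under about 0.43 FPKM. The implied standard error had a median of 0.67 on the log2 scale for genes whose higher value was 1 to 5 FPKM, 0.42 for 5 to 20 FPKM and 0.31 from 20 FPKM, and 11.6%, 6.55% and 6.71% of the genes of these classes were at least 2-fold apart.

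The log2 ratio of distal over proximal was computed as log2((distal FPKM + 1)/(proximal FPKM + 1)), which understates differences of low genes. Genes with at least 1 FPKM in 1 library were called measured, and a log2 ratio of at least 1 in either direction was counted as at least 2-fold. Folds printed beside FPKM values are plain ratios of those values. No test of the regions was made, since each group had 1 library. Calls and q-values are those of the authors' deposited table.

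For each of 33 gene lists the median log2 ratio was placed among the medians of 10000 random lists of the same size, drawn with replacement from measured genes within 20 bins of mean log2(FPKM + 1). A list outside the central 95% was said to stand apart, as a description of these libraries. Tested on simulated log2 ratios of 9847 genes, lists of 25 genes fell outside that range in 4 of 100 cases with no shift and in 100 of 100 cases with a shift of 0.5. In this simulation lists were random and genes varied independently, and no other list size was tried. The rates therefore do not carry over to lists of genes that act together. Hox paralogue groups 10 to 13 were compared with groups 1 to 9 by the difference of medians among genes with at least 0.5 FPKM in 1 library, placed among 100000 relabellings of the same genes. Intervals of medians in the closing part are from 10000 bootstrap draws over genes. They treat genes as independent and do not measure variation between rats or preparations.

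The lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule takes the 10 highest and 10 lowest log2 ratios among tested genes with at least 5 FPKM in 1 library, up to 4 measured members of each list by absolute log2 ratio, up to 20 proto-oncogenes at least 2-fold apart or called in the deposited table, and 17 genes named in advance whatever their values. Some genes that the rule selects are not reported here. Alternatives were a pseudocount of 0.1 or 5 FPKM, rescaling the distal library to a median log2 ratio of 0 or to the same upper quartile, tested genes only, summed rows of a symbol, no minimum or a minimum of 5 FPKM, a 1.5-fold or 4-fold threshold, and a q of 0.01. Chosen after the data were seen were the versions without microRNA precursors, without genes that share a locus and without genes listed at 0 in either library. The analysis used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.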

Results

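RNA was sequenced from crypts of the proximal and of the distal colon of Sprague Dawley rats, an outbred laboratory strain, at 14 weeks of age. Colon crypts are the epithelial pits that hold the stem, absorptive, goblet and hormone-producing cells of the colon. Each region gave 1 RNA library from the pooled material of 7 rats. With 1 library per region there was no spread between replicates, so the differences below have no replicate check and compare these 2 libraries. The series title asks how histone marks and the expression of proto-oncogenes differ between the ends of the colon. The 5 chromatin immunoprecipitation libraries of the series, for H3K4me3, H3K9me3 and RNA polymerase II, were not analysed here.

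Gene expression in the 2 regions was similar across most genes, and genes at least 2-fold apart included positional Hox genes, antimicrobial proteins, mucus genes, ion and water transporters and lymphocyte markers. Of 9847 genes with at least 1 FPKM (fragments scaled by transcript length and library size) in 1 library, 82.7% differed by less than 1.5-fold. This share was taken on the log2(FPKM + 1) scale, which understates differences of low genes. Counts of genes at least or less than 2-fold apart use this scale throughout. On the log2(FPKM + 1) scale 365 genes were at least 2-fold higher in the distal library and 385 in the proximal library, together 7.62% of these genes, 48.7% of them higher in the distal library. This share was 41.4% and 39.8% when the distal library was rescaled to a median log2 ratio of 0 or to the same upper quartile, and 44.0% with a pseudocount of 0.1 FPKM (484 and 617 genes). It turned to 60.9% with a pseudocount of 5 FPKM (196 and 126 genes), 55.0% with a minimum of 5 FPKM (289 and 236 genes), 53.1% at 1.5-fold and 54.0% at 4-fold, so neither library was higher for more genes under all settings. Across genes, which are not independent replicates, the log2(FPKM + 1) values of the libraries had a Pearson r of 0.936 and a Spearman rho of 0.944. The median log2 ratio of distal over proximal was 0.09. The authors' deposited table called 548 rows significant, up to a q of 0.0495, of which 276 were higher in the distal and 272 in the proximal library. Of the genes at least 2-fold apart, that table called 245 of the 365 and 243 of the 385, and did not call the other 262.

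**Figure D1:**
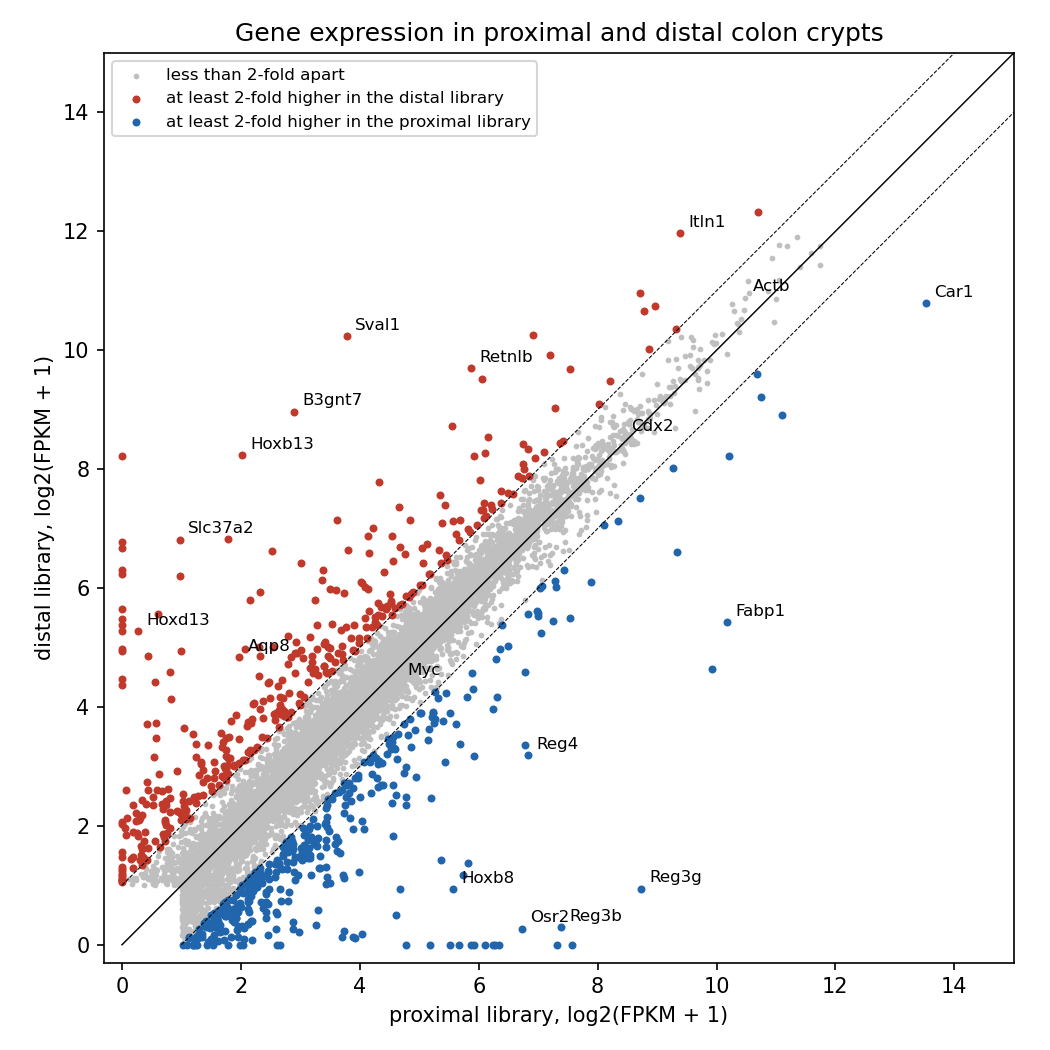
Each point is 1 of 9847 genes, with its log2(FPKM + 1) in the proximal library on the x axis and in the distal library on the y axis; red and blue points are the 365 and 385 genes at least 2-fold higher in the distal and in the proximal library, and dashed lines mark 2-fold differences. Hoxb13, at 3.06 and 301 FPKM, lies far above the diagonal, and Reg3g, at 425 and 0.925 FPKM, far below it.

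Among the genes furthest apart, the distal library was higher for Sval1, at 1210 against 12.8 FPKM (94.9-fold), for Hoxb13, at 301 against 3.06 FPKM (98.5-fold), and for B3gnt7, at 499 against 6.43 FPKM (77.6-fold). B3gnt7 encodes a glycosyltransferase that extends sugar chains. Slc37a2, a sugar phosphate transporter, stood at 111 FPKM in the distal and 0.961 FPKM in the proximal library. The proximal library was higher for the antimicrobial lectins Reg3g, at 425 against 0.925 FPKM, and Reg3b, at 167 against 0.233 FPKM, and for the transcription factor Osr2, at 105 against 0.207 FPKM. For Hoxb13 the authors' deposited table gave a log2 fold change of 6.62, for which its test statistic implied a standard error of 0.53, and for Reg3g it gave -8.84 with an implied 0.67. The other 13 of the 20 genes that the rule on extremes selected were microRNA precursors, each listed at 0 in 1 library, such as Mir23a at 0 and 296 FPKM and Mir1224 at 190 and 0 FPKM. After the values were seen, the rule was therefore also applied without microRNA precursors. The wider rule added Scgb1a1 (0.955 and 72.6 FPKM in the proximal and distal library), Tgm3 (2.43 and 112 FPKM), Vsig1 (4.78 and 98.1 FPKM) and Sstr1 (3.43 and 55.0 FPKM) on the distal side. On the proximal side it added LOC691277 (968 and 23.8 FPKM), Napsa (52.4 and 1.27 FPKM), Bmper (14.2 and 0.0840 FPKM) and Slc13a1, a sulfate transporter (24.5 and 0.911 FPKM). Of these added genes, Sstr1, Bmper and Slc13a1 lay beyond the first 10 on their side.

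Hox genes, which mark position along the body axis, differed largely by paralogue group. All 5 measured members of groups 10 to 13 were at least 2-fold higher in the distal library, with a median log2 ratio of 2.53, above all 10000 random lists matched on expression (percentile 100). This median was 1.53 with a pseudocount of 5 FPKM and 5.13 with 0.1 FPKM. Besides Hoxb13, on chromosome 10 at 84925520 to 84927793 of the rn4 build, they included Hoxd13, on chromosome 3 at 57283682 to 57286998, at 0.200 and 37.7 FPKM in the proximal and distal library. Hoxd10 stood at 0.0470 and 5.05 FPKM, and Hoxa10, which shares its locus in the table with another gene, at 7.09 and 29.9 FPKM. Of the 11 measured members of groups 1 to 9, 6 were at least 2-fold higher in the proximal library and 1 in the distal library, with a median of -2.10 (percentile 0). The median was -0.94 with a pseudocount of 5 FPKM, -4.52 with 0.1 FPKM and -0.20 over 17 genes with no minimum, still below the central 95%. Hoxb8 stood at 46.5 and 0.916 FPKM (50.8-fold higher in the proximal library), Hoxb7 at 55.2 and 1.59 FPKM (34.8-fold), Hoxb5 at 23.4 and 0.422 FPKM and Hoxb4 at 15.4 and 0.138 FPKM. Among the anterior genes not 2-fold higher in the proximal library, chosen after their values were seen, Hoxa6 stood at 35.3 and 52.5 FPKM, Hoxa9 at 86.5 and 78.4 FPKM, and Hoxd9 at 0 and 1.47 FPKM. The authors' deposited table called 3 of the posterior genes higher in the distal and 7 of the anterior genes higher in the proximal library. Hoxb6 was not analysed here.

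**Figure D2:**
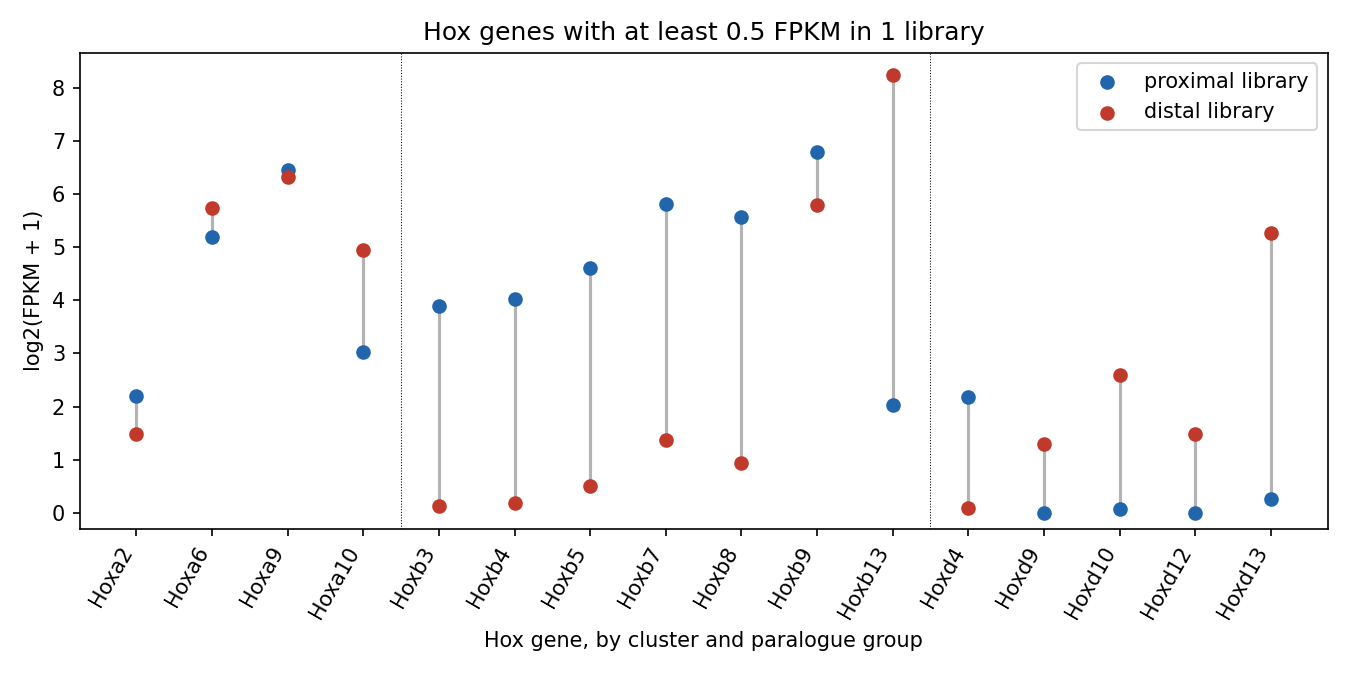
The 16 Hox genes with at least 0.5 FPKM in 1 library, ordered by cluster and paralogue group along the x axis, with log2(FPKM + 1) in the proximal (blue) and distal (red) library on the y axis and a grey line joining the values of each gene. The posterior genes Hoxa10, Hoxb13, Hoxd10, Hoxd12 and Hoxd13 were higher in the distal library, and Hoxb3 to Hoxb9 higher in the proximal library.

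Genes of sodium uptake and the aldosterone response were higher in the distal library, with a median log2 ratio of 0.52 over 16 measured members (percentile 100). At least 2-fold higher were 4 of them: Fxyd4, a regulator of the sodium pump, at 0.354 and 28.1 FPKM in the proximal and distal library, Tsc22d3, a steroid-induced gene, at 9.27 and 69.2 FPKM (7.46-fold), and the epithelial sodium channel subunits Scnn1a, at 22.5 and 86.9 FPKM (3.86-fold), and Scnn1b, at 2.31 and 6.87 FPKM (2.97-fold). The authors' deposited table called 3 of these, and not Scnn1b. None was 2-fold higher in the proximal library. Water channels had a median of 0.73 over 5 measured members (percentile 99.8), with Aqp8 at 2.93 and 27.5 FPKM (9.39-fold) and Aqp3 at 16.5 and 116 FPKM (7.00-fold), while Aqp1 stood at 72.6 and 41.0 FPKM. With a pseudocount of 5 FPKM the median fell inside the central 95% (0.24, percentile 89.5). For Aqp8 the authors' deposited table gave a log2 fold change of 3.23, an implied standard error of 0.53 and a q of 1.73e-07.

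Genes of anion, bicarbonate and potassium transport went both ways, with 3 of 23 measured members at least 2-fold higher in the distal and 5 in the proximal library and a median of -0.18 (percentile 0.015) against a mean of 0.04. The median was -0.04 over 29 members with no minimum and -0.32 with equal upper quartiles, below the central 95% in both cases. Car1, a carbonic anhydrase, stood at 11730 FPKM in the proximal and 1781 FPKM in the distal library (6.59-fold). Higher in the distal library were the potassium pump Atp12a, at 0.470 and 20.4 FPKM, and the anion channels Best2, at 0.740 and 23.0 FPKM (31.0-fold), and Ano1, at 16.0 and 63.7 FPKM (3.99-fold). The chloride and bicarbonate exchanger Slc26a3 was less than 2-fold apart, at 226 and 179 FPKM. For Car1 the authors' deposited table gave a log2 fold change of -2.72, an implied standard error of 0.41 and a q of 7.80e-09.

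Goblet cell and mucin genes were mostly higher in the distal library: 9 of 21 measured members were at least 2-fold higher there and 3 in the proximal library, with a median log2 ratio of 0.83 (percentile 100). Retnlb, which encodes the goblet cell product RELM beta, stood at 57.8 and 834 FPKM in the proximal and distal library (14.4-fold), the sulfotransferase Chst5 at 0.530 and 46.5 FPKM (87.8-fold) and the membrane mucin Muc1 at 3.97 and 27.8 FPKM (7.01-fold). Reg4 was higher in the proximal library, at 113 against 8.08 FPKM (14.0-fold). The authors' deposited table called 6 members higher in the distal and 2 in the proximal library. Muc2 was not analysed here.

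Antimicrobial and innate defence genes were split, with 10 of 30 measured members at least 2-fold higher in the distal and 6 in the proximal library. Their median was 0.49 (percentile 100) and their mean 0.03, since Reg3g and Reg3b lay far on the proximal side. With no minimum the median of 42 members was 0.065, inside the central 95% (percentile 91.8). Lbp, the lipopolysaccharide-binding protein, stood at 0.335 and 12.1 FPKM and the chemokine Ccl6 at 45.8 and 422 FPKM (9.22-fold), both higher in the distal library. The authors' deposited table called 8 members higher in the distal and 5 in the proximal library.

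Markers of hormone-producing cells were mostly lower in the distal library, with a median log2 ratio of -0.45 over 19 measured members (percentile 0.010; -0.17 over 26 with no minimum), of which 5 were at least 2-fold higher in the proximal and 2 in the distal library. Chromogranin genes stood at 150 and 42.6 FPKM for Chgb (3.53-fold higher in the proximal library) and at 89.1 and 31.6 FPKM for Chga (2.82-fold). The monoamine transporter Slc18a1 stood at 26.6 and 4.08 FPKM (6.52-fold) and Tph1, the enzyme that starts serotonin synthesis outside the brain, at 17.3 and 4.87 FPKM (3.54-fold). The authors' deposited table called these 4. Insl5 was not analysed here. Tuft cell markers had a median of 0.35 over 12 members (percentile 99.4; 0.21 and percentile 96.6 over 14 with no minimum), and the only member at least 2-fold apart was Cd24, at 501 and 1717 FPKM, which is not confined to tuft cells.

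Absorptive colonocyte genes had a median of 0.26 over 25 measured members (percentile 92.6), or 0.35 over 24 without genes sharing a locus (percentile 99.3), with 4 at least 2-fold higher in the distal and 1 in the proximal library. Besides Slc37a2, the peptidase Dpp4 stood at 15.5 and 67.0 FPKM (4.32-fold) and the tight junction gene Cldn4 at 55.4 and 127 FPKM (2.29-fold), while Tmigd1 stood at 108 and 23.1 FPKM (4.69-fold higher in the proximal library). Gut transcription factors had a median of 0.10 over 21 members (percentile 27.9), which turned negative under both rescalings of the libraries. Without the 1 member that shares its locus with another gene the median was -0.051, below the central 95% (percentile 0.56). Cdx2, at 342 and 370 FPKM, differed by less than 2-fold, whereas Foxa2 was higher in the distal library (8.76 and 40.5 FPKM, 4.62-fold) and Tbx3 in the proximal library (10.3 and 1.06 FPKM, 9.73-fold).

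Stem cell and Wnt target genes had a median of -0.014 over 17 measured members (percentile 9.19). Lgr5, a marker of crypt stem cells, stood at 1.73 and 1.52 FPKM, Ascl2 at 2.93 and 9.95 FPKM, Cd44 at 48.1 and 12.1 FPKM (3.97-fold higher in the proximal library) and Olfm4 at 3.33 and 0.276 FPKM. Of 23 Wnt pathway genes, 2 were at least 2-fold higher in the distal library, namely the secreted Wnt modulator Sfrp2 at 0.988 and 29.5 FPKM (29.9-fold) and Wnt11 at 0.221 and 3.29 FPKM, and 1 in the proximal library, Wnt5a at 7.37 and 2.58 FPKM, with a median of -0.07 (percentile 5.54). With a minimum of 5 FPKM the list lay just below the central 95% (-0.066 over 17 members, percentile 2.495), and with no minimum its median was 0 (percentile 44.3). Notch, BMP and hedgehog genes had a median of 0.08 over 27 members (percentile 38.7), negative under both rescalings. It stood above the central 95% with a minimum of 5 FPKM (0.29, percentile 99.1) and without genes sharing a locus (0.25, percentile 97.7). Bmp2 stood at 4.82 and 31.3 FPKM (6.50-fold), the Notch ligand Dll1 at 2.38 and 8.67 FPKM (3.65-fold), the BMP target Id1 at 259 and 545 FPKM (2.10-fold), and Bmp3 at 23.5 and 7.68 FPKM (3.07-fold higher in the proximal library).

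Proto-oncogenes as a group were not displaced towards either library. Of 93 measured members, 6 were at least 2-fold higher in the distal and 7 in the proximal library. The median log2 ratio of 0.13 (percentile 84.8) changed sign when the upper quartiles of the libraries were equalised. Together the members at least 2-fold apart were a larger share of the list than the 7.62% among all measured genes. Whether this larger share stands out was not tested. Higher in the distal library were Maf (4.20 and 13.1 FPKM, 3.12-fold), Rhob (21.8 and 58.6 FPKM, 2.69-fold), Jun (64.8 and 159 FPKM, 2.45-fold), Ccnd2, a G1 cyclin (22.1 and 52.7 FPKM, 2.38-fold), and Fos (108 and 256 FPKM, 2.38-fold). The remaining member on this side, Rhoc, at 99.9 and 235 FPKM, shares its locus in the table with another gene. Higher in the proximal library were Vav2 (3.35 and 0.279 FPKM), Pdgfrb (2.499 and 0.410 FPKM), Fli1 (1.61 and 0.283 FPKM), Lmo1 (7.80 and 2.10 FPKM, 3.72-fold), Ets1 (5.23 and 1.55 FPKM, 3.38-fold), Fgr (3.60 and 1.10 FPKM, 3.28-fold) and Etv5 (27.1 and 10.6 FPKM, 2.57-fold). Ets1, Fli1 and Fgr are also expressed in blood cells, and lymphocyte markers, given below, were lower in the distal library. Fos and Jun are also immediate early genes. That group, given below, was higher in the distal library, and an effect of handling on it stays open. The authors' deposited table called all 6 on the distal side and 5 on the proximal side, leaving out Lmo1 and Fgr. Myc stood at 24.3 and 20.6 FPKM, less than 2-fold apart and not called.

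Tumour suppressor genes had a median of -0.0032 over 40 measured members (percentile 4.85), or 0.05 over 32 with a minimum of 5 FPKM (percentile 12.7), and 4 were at least 2-fold higher in the distal library, none in the proximal library. They were Sfrp2, Ndrg2 (12.96 and 99.3 FPKM, 7.66-fold), the DNA repair gene Mgmt (4.18 and 16.1 FPKM, 3.85-fold) and Klf4, a factor of epithelial differentiation (171 and 356 FPKM, 2.09-fold).

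Enzymes that write, erase or bind methyl marks on H3K4 and H3K9 differed by less than 2-fold in all 25 measured cases, with a median of 0.13 (percentile 65.5) that turned negative when the upper quartiles were equalised. The demethylase gene Kdm1b, at 13.4 and 18.9 FPKM, was the furthest apart. DNA methylation and Polycomb genes were also less than 2-fold apart in all 21 cases (median 0.19, percentile 83.1; 0.04 with equal upper quartiles), with Mbd2 at 105 and 156 FPKM. Of 39 proliferation genes, 38 were less than 2-fold apart (median 0.14, percentile 82.3; 7.49e-05 with equal upper quartiles), the exception being the thymidylate synthase gene Tyms, at 42.9 and 17.7 FPKM. Mki67 was not analysed here. Housekeeping genes had a median of 0.23 over 19 members (percentile 85.4), or 0.08 with equal upper quartiles, none of them 2-fold apart, with Actb at 1425 and 1890 FPKM. Gapdh, which has many processed copies in the rat genome, was listed at 2.74 and 3.56 FPKM. Genes for ribosomal proteins and for oxidative phosphorylation had medians of 0.03 over 61 members (percentile 0.47) and 0.05 over 50 members (percentile 0.90), low against random lists and negative under both rescalings. On the log2(FPKM + 1) scale Rpl39, at 0.758 and 4.54 FPKM, was the only member of either list at least 2-fold apart. As plain ratios other low members were also over 2-fold apart, such as Rps20 (0.525 and 1.81 FPKM), Rpl13 (1.03 and 2.93 FPKM) and Rpl38 (7.08 and 3.05 FPKM).

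Genes of nutrient, bile acid and lipid handling were lower in the distal library, with 5 of 18 measured members at least 2-fold higher in the proximal and 1 in the distal library and a median of -0.17 (percentile 0.99), or -0.11 over 27 with no minimum and -0.29 with equal upper quartiles. Fabp1, a fatty acid-binding protein, stood at 1153 and 42.2 FPKM (27.3-fold higher in the proximal library) and Ostalpha, a subunit of a bile acid exporter, at 59.4 and 8.06 FPKM (7.37-fold). For Fabp1 the authors' deposited table gave a log2 fold change of -4.77 with an implied standard error of 0.41. Short-chain fatty acid and ketone body genes had a median of 0.17 over 17 members (percentile 55.8), or 0.02 with equal upper quartiles, with 4 at least 2-fold higher in the distal library, among them the butyrate transporter Slc5a8 (66.3 and 157 FPKM, 2.38-fold) and the receptor Ffar2 (11.4 and 29.0 FPKM, 2.55-fold). Cholesterol synthesis genes were higher in the distal library in 20 of 22 cases, by small amounts (median 0.40, percentile 100; 0.25 with equal upper quartiles), as for Hmgcs1 at 48.4 and 90.5 FPKM (1.87-fold).

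Xenobiotic metabolism genes were lower in the distal library, with 13 of 49 measured members at least 2-fold higher in the proximal and 3 in the distal library and a median of -0.24 (percentile 0). The median was -0.07 over 65 members with no minimum and -0.38 with equal upper quartiles (percentile 0 in both cases). The glutathione transferase gene Gsta5 stood at 40.2 and 1.70 FPKM (23.7-fold higher in the proximal library) and Cyp4f1 at 184 and 44.3 FPKM (4.15-fold), while the alcohol dehydrogenase gene Adh1 stood at 146 and 972 FPKM (6.66-fold higher in the distal library). Immediate early and heat shock genes had a median of 0.43 over 29 members (percentile 100), and 6 were at least 2-fold higher in the distal library, including Atf3 (12.5 and 39.7 FPKM, 3.16-fold), Dusp1 (67.0 and 172 FPKM, 2.57-fold) and Klf2 (4.88 and 13.8 FPKM, 2.82-fold).

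Lymphocyte markers were lower in the distal library: 17 of 26 measured members were at least 2-fold higher in the proximal library and none in the distal library, with a median of -1.43 (percentile 0), or -0.54 with a pseudocount of 5 FPKM and -2.17 with 0.1 FPKM. B-cell genes stood at 8.80 and 0.502 FPKM for Cd79b (17.5-fold higher in the proximal library) and at 6.32 and 0.202 FPKM for Ms4a1, and Gzma, of cytotoxic lymphocytes, at 26.3 and 4.58 FPKM (5.76-fold). The authors' deposited table called 14 members higher in the proximal library. Myeloid and mast cell markers had a median of -0.57 over 20 members (percentile 0.020), or -0.15 over 34 with no minimum, with the mast cell protease gene Mcpt1 at 59.2 and 18.7 FPKM (3.17-fold) and Cpa3 at 7.42 and 2.00 FPKM (3.71-fold). Interferon and antigen presentation genes had a median of -0.13 over 34 members (percentile 0.050), or -0.26 with equal upper quartiles. The class II genes Cd74 (131 and 37.0 FPKM, 3.53-fold), RT1-Da (36.8 and 12.2 FPKM, 3.01-fold) and RT1-Db1 (12.3 and 3.63 FPKM, 3.38-fold) were higher in the proximal library, and the interferon-induced Ifi27 (11.2 and 61.7 FPKM, 5.52-fold) in the distal library.

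Fibroblast and smooth muscle markers had a median of 0.02 over 9 measured members (percentile 58.1), negative under both rescalings, with Des at 0.0398 and 2.91 FPKM and Vim at 13.6 and 7.07 FPKM. Markers of endothelium, blood, nerve and fat had a median of 0.13 over 10 members (percentile 79.1), which was 0.96 with a minimum of 5 FPKM (percentile 99.7), -0.012 with no minimum and -0.18 without genes sharing a locus. Examples were Esam at 6.54 and 22.9 FPKM (3.50-fold) and the haemoglobin gene Hba-a2 at 56.3 and 101 FPKM. Small intestine and pancreas markers had a median of -0.74 over 10 members (percentile 0), where the defensin gene Defa6, at 41.1 and 12.6 FPKM, was higher in the proximal library, and the authors' deposited table called none of the 10. With no minimum the median of 25 members was 0 (percentile 49.9).

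**Figure D3:**
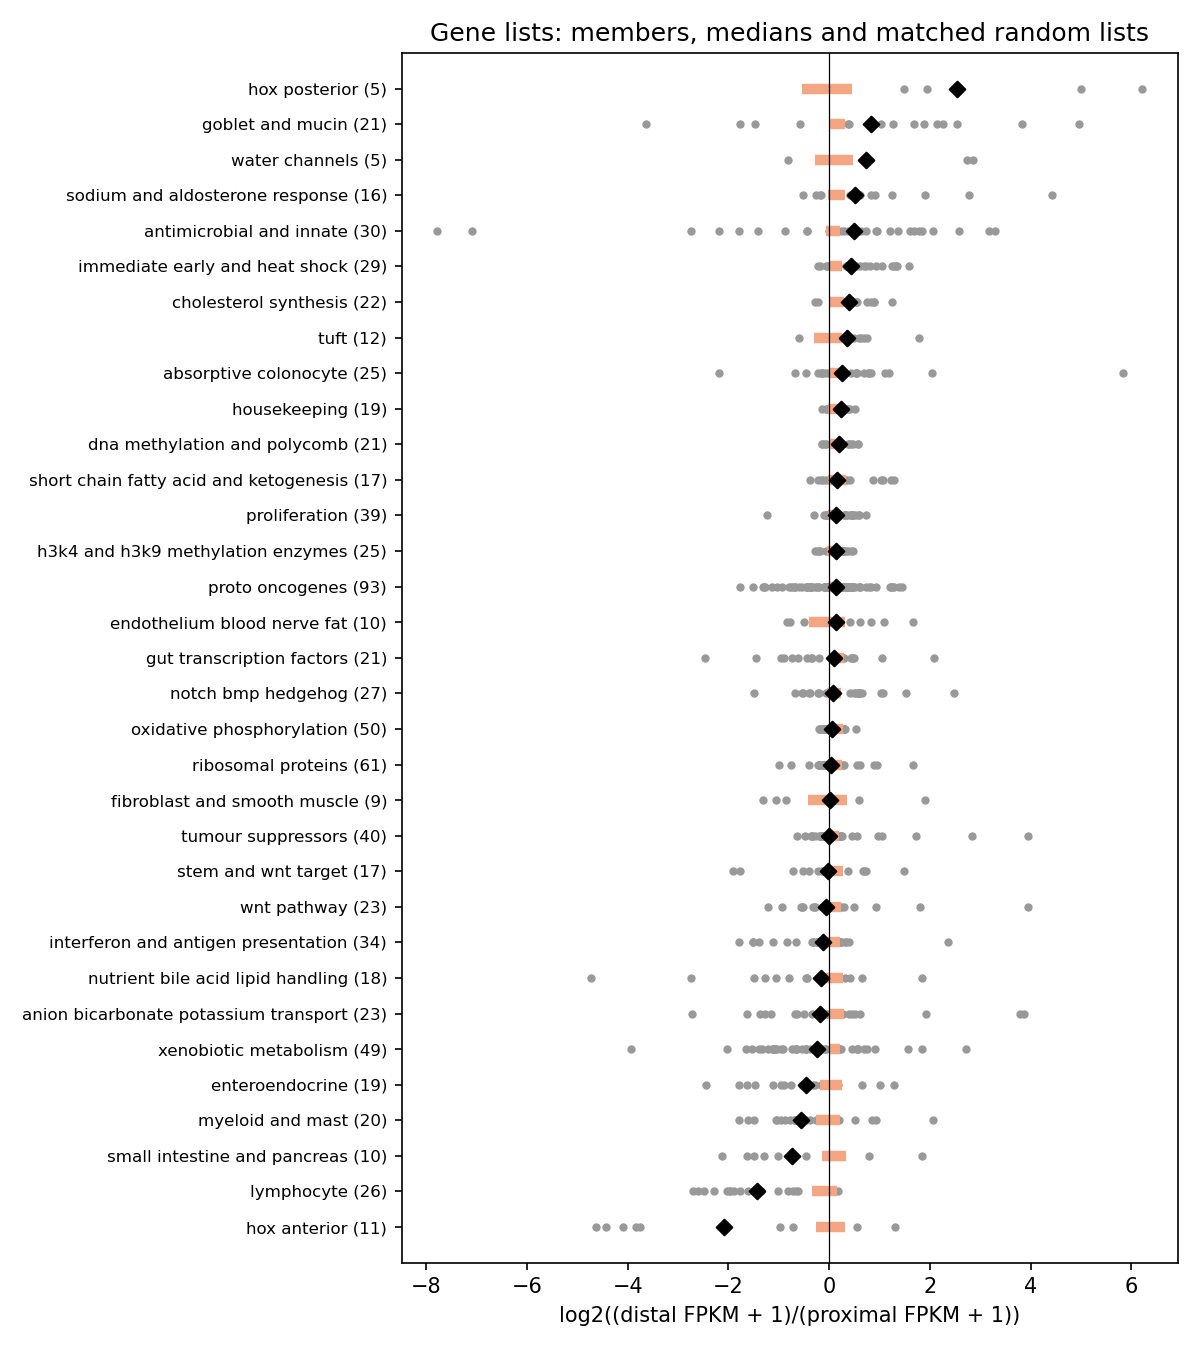
Each row is 1 of 33 gene lists with the number of measured members in brackets; the x axis is the log2 ratio of distal over proximal FPKM, each with 1 added, grey points are members, black diamonds list medians, and orange bars the central 95% of medians of 10000 random lists matched on expression. The medians of 19 lists lie outside their bars, from -2.10 for the anterior to 2.53 for the posterior Hox genes.

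Of the 33 lists, 19 had a median outside the central 95% of their random lists, against 1.65 expected if lists were random draws. The lists share members and genes act together, so their percentiles describe these libraries and are not tests of the regions.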

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

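The versions without microRNA precursors, without genes sharing a locus and without genes listed at 0 were chosen after the data were seen. With 1 library per region no version measures variation between animals, and for genes of about 942 bases 3 reads stand near 0.426 FPKM in the proximal and 0.339 FPKM in the distal library. Rescaling moved the plain log2 ratios of FPKM by -0.11 (median) or -0.15 (upper quartile), and those of low genes by less once 1 FPKM is added. The counts of genes at least 2-fold higher in the distal and proximal library, 365 and 385 as reported, stayed within 1.5 times of these under either rescaling, with tested genes only, with summed rows, with no minimum and in the versions added later. Otherwise the proximal count was 617 with a pseudocount of 0.1 FPKM and 236 with a minimum of 5 FPKM, and the counts were 196 and 126 with a pseudocount of 5 FPKM, 905 and 800 at 1.5-fold and 87 and 74 at 4-fold, where the shrinkage of low genes, the minimum and the threshold act by construction. With a pseudocount of 5 FPKM 60.9% of these genes were higher in the distal library, and 41.4% and 39.8% under the rescalings, against 48.7% as reported. The authors' deposited table held 352 calls at a q under 0.01. The correlation of the libraries was 0.903 with a pseudocount of 0.1 FPKM and 0.976 with no minimum.

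Of 297 list medians under alternatives, 267 kept their direction and their side of the central 95%. The distal library rescaled to a median of 0 turned the medians of gut transcription factors to -0.0084, Notch, BMP and hedgehog genes to -0.023, fibroblast markers to -0.061, ribosomal proteins to -0.084 and oxidative phosphorylation to -0.062. Equal upper quartiles turned them to -0.044, -0.058, -0.081, -0.12 and -0.098 in the same order, and those of proto-oncogenes to -0.0096 and of H3K4 and H3K9 enzymes to -0.0079. These reversals follow from the shift, which exceeds the medians. Water channels no longer stood apart with a pseudocount of 5 FPKM (0.24), nor tuft (0.21), antimicrobial (0.065) and small intestine markers (0) with no minimum. There the medians of gut transcription factors, Wnt pathway, Notch, BMP and hedgehog genes, tumour suppressors and fibroblast markers were also 0, and that of endothelium, blood, nerve and fat was -0.012. With a minimum of 5 FPKM the medians of Wnt pathway genes (-0.066), Notch, BMP and hedgehog genes (0.29) and endothelium, blood, nerve and fat (0.96) stood apart and that of tumour suppressors was 0.053. Without genes sharing a locus those of absorptive (0.35) and Notch, BMP and hedgehog genes (0.25) stood apart on the high side and that of gut transcription factors (-0.051, percentile 0.56) on the low side, and endothelium, blood, nerve and fat gave -0.18 (percentile 29.7). Of the medians that kept their side of the central 95%, 31, of 12 lists that stood apart, moved over 1.5 times, such as lymphocyte markers (-0.54 with a pseudocount of 5 FPKM). Apart from the rescalings, the cause was not tested. Of 990 values of 165 named genes, 113 moved by more than the implied standard error, under the 2 pseudocounts, and none at least 2-fold apart changed sign. The Hox difference was 2.43 with no minimum and 9.65 with a pseudocount of 0.1 FPKM. No paired analysis was possible because each region had 1 library.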

Other observations

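Some of the most abundant transcripts also differed. Among the 200 genes with the highest FPKM in either library, 22 were at least 2-fold higher in the distal and 11 in the proximal library. These counts include the microRNA precursors Mir632 on the distal and Mir196c on the proximal side. Of all genes whose higher value was 20 FPKM or more, 6.71% were at least 2-fold apart. Genes entered both sets by the higher of their 2 values, which favours genes that differ. Unless stated otherwise, the genes named in this paragraph were chosen after their values were seen, also where they belong to a fixed list. Txn1, which encodes thioredoxin, stood at 1666 FPKM in the proximal and 5132 FPKM in the distal library, and the lectin gene Itln1 at 671 and 4023 FPKM. Retnla, a relative of Retnlb, stood at 120 and 1226 FPKM, Nov, a secreted matrix protein gene, at 65.6 and 732 FPKM, and Cd9 at 69.9 and 372 FPKM. Mucus genes among them were Clca1, at 417 and 1992 FPKM, Fcgbp, at 185 and 820 FPKM, and Tff3, at 438 and 1618 FPKM, of which the authors' deposited table called only Tff3. On the proximal side were the mucosal scavenger gene Dmbt1, at 2193 and 481 FPKM, the peroxiredoxin gene Prdx6, at 1183 and 296 FPKM, the selenium-binding gene Selenbp1, at 1634 and 776 FPKM, and S100g, a calcium-binding protein gene that shares its locus with another gene, at 644 and 96.2 FPKM. Mir196c, at 1728 and 592 FPKM, lies at 84995948 to 84996027 of chromosome 10, next to Hoxb9, which starts at 85002254 and stood at 109 and 54.6 FPKM. On such short precursors few reads give a high FPKM. The precursor Mir760, selected by the rule on extremes, stood at 74.7 FPKM in the distal library with the p-value taken to mark 1 read. The values of Mir196c are therefore not a measure of abundance comparable with those of longer genes.

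The tests below were chosen after the results they bear on had been seen, except those of the second lymphocyte list and of neighbouring genes, and for the Hox genes the direction but not the bound was fixed before the data were examined.

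Posterior Hox genes were predicted to be higher in the distal library. The median log2 ratio of 5 genes of groups 10 to 13 exceeded that of 11 genes of groups 1 to 9 by 4.63. This difference lay above that of 99.477% of relabellings of the same genes. Genes of 1 cluster are not independent of each other, so the figure describes these genes in these libraries.

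Lymphocyte markers were lower in the distal library (median -1.43). A lower share of epithelial cells in the proximal preparation would raise all other cell types there alike. Stromal, endothelial, blood, nerve and fat markers, 19 of 67 measured, exceeded the lymphocyte median by 1.45 (95% bootstrap interval 0.72 to 2.07). In these 2 libraries this argues against a lower epithelial share for those cell types. The interval is from draws over genes, which are not independent, and does not measure variation between rats or preparations. At least 5 FPKM in 1 library was reached by only 3 fibroblast and smooth muscle markers and 4 of endothelium, blood, nerve and fat. Myeloid and mast cell markers, which were not part of this comparison, were also lower in the distal library (median -0.57). Lymphoid cells in the proximal preparation may account for the pattern. A second list held 28 measured leukocyte genes, none of them in a fixed list and 15 at 1 FPKM or more in both libraries. Its median was -1.20 (percentile 0), with Coro1a at 20.1 and 5.40 FPKM and Rac2, an exception, at 42.9 and 52.2 FPKM. This list was read in the same 2 libraries and holds genes of the same kinds of cells, so it is not independent support. As a list of leukocyte genes it does not separate lymphoid from myeloid cells. B-cell markers lay below T and NK cell markers by -1.11 (interval -1.89 to -0.22), as B-cell-rich lymphoid tissue would give. This comparison was made only with 1 FPKM added, which shrinks the ratios of low genes. Expression level may therefore add to the gap, and its interval too is over genes that are not independent. Genes of lymphoid and antigen-presenting cells in the proximal library included Cd74 at 131 FPKM, Gzma at 26.3 FPKM, Ccl5 at 24.1 FPKM, Faim3 at 9.81 FPKM and Cd79b at 8.80 FPKM. Whether such cells were part of the isolated material or differ between regions in the animal stays open and untested.

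Immediate early genes were higher in the distal library, with a median of 0.61 over 21 genes (percentile 100). Rescaling the distal library to a median log2 ratio of 0 over all genes left a median of 0.49 (95% bootstrap interval 0.33 to 0.82). That rescaling moved plain log2 ratios by only -0.11, so this outcome followed from the sizes and is no separate test. A scaling offset of that size is too small to be the whole cause. The 5 measured of 8 heat shock genes had a median of 0.027 (interval -0.19 to 0.43), below that of the immediate early genes. This argues against a heat shock response during isolation as large as the immediate early difference. The interval still holds a smaller rise, so these few genes cannot exclude one. A smaller heat shock response, handling that acts on immediate early genes alone, and a regional difference stay open.

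MicroRNA precursors had large ratios. Of 29 precursors at least 2-fold apart, 86.2% were listed at 0 in 1 library and the authors' deposited table called 0, against 67.7% called of the other 721 genes at least 2-fold apart. Single reads on very short transcripts are a candidate explanation for some of them. Of the 8 precursors at 0 in 1 library that lie alone at their locus, 6 (75%) had the p-value of the authors' deposited table that was taken to mark 1 read, whereas Mir23a (0.0484) and Mir27a (0.0876) had lower ones, which goes against a single read for these 2. Of the 17 that share a locus none had that p-value of the authors' deposited table: Mir3074 (0.0969) and Mir3556b (0.105), 11.8% of them, had lower ones, which goes against a single read in the same way. The other 15 had higher ones, and for these the explanation stays open, as does a biological one, which was not tested. Mir29c (0 and 49.1 FPKM) and Mir3556b (59.4 and 0 FPKM) are listed at the same locus, chromosome 13 at 110968040 to 110968146. That locus had values above 0 in both libraries, under different symbols. The opposite ratios of this pair therefore do not show that the stretch was transcribed in only 1 library.

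Neighbouring genes differed together to a small degree. Over 9078 pairs of adjacent measured genes that share neither a locus nor a name stem, the log2 ratios had a Pearson r of 0.077 across genes, above the highest of 1000 shuffles of gene order over the same pairs (0.048), and a Spearman rho of 0.098, above the highest of its own shuffles (0.037). With pairs of related names the r was 0.14 over 9396 pairs. Why neighbours resembled each other was not tested.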
